A study of Mus musculus with 6 samples.

How the data were processed

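Total RNA from 3 macrophage and 3 Kit+ progenitor cultures of mouse bone marrow, each after 4 days of culture, was amplified, labelled with biotin and hybridized to exon arrays, 1 array per sample, per the labels' protocols. The values deposited by the authors are intensity values per probe set on a linear scale. Affymetrix Expression Console and RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes) are named in the submitters' processing notes, with no version or setting given. The genome build and filters are not given in the sources used here, so no coordinates are printed. RMA draws the arrays to a common distribution, which can hide a change in total RNA per cell, and array signal is compressed at low and high levels, which understates folds there. Per-array medians and the number of arrays, 6, set the precision, as arrays have no read depth.

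Samples were grouped by their titles. The label of Kit+ replicate 1's raw data carries a suffix that the other 5 lack, so a repeat hybridization or scan of that sample is not excluded. They carry numbers 1 to 3 in each group. The series text calls them biological samples, and whether they came from separate mice is not given in the sources used here, so p-values measure the spread between these samples. At least 99.95% of probe sets differed in value between any pair of arrays, so no array was a copy of another.

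Intensities were taken to log2, with no further normalization. Of 194293 probe sets, 179614 carried 1 gene symbol in the platform annotation given, 1331 several and 13348 none. Probe sets without a single symbol were left out of gene tests. Of the gene symbols, 13745 were current in a RefSeq table of the mouse, 2021 older ones were updated through its synonyms and 64 were kept as given. The value of a gene was the median log2 value of its probe sets, with a median of 9 probe sets per gene, over 15830 genes. The test was limma (version 3.58.1, R 4.3.3), lmFit and eBayes with default settings, macrophage against Kit+, two-sided, with Benjamini-Hochberg adjustment over all genes and calls at adjusted p under 0.05. SDs are over 3 samples and SEs are those of the moderated fit. Probe sets of a gene disagreed in direction, each past the threshold, in 83 genes.

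Fixed before the data were examined were 35 gene lists, 7 of them on retinoids and the others on cell types, growth and stress. Lists with 5 or more genes measured were tested with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35. The call was repeated with an estimated correlation and with fry, whose directional test asks whether a list's genes move one way and does not compare the list with other genes. With the estimated correlation 4 lists of the 17 passed: macrophage markers, lysosome genes, primary granule and promyelocyte genes, and mast cell and basophil genes. Members are counted after adjustment over all genes and over the list alone. Some genes stand in several lists. Olfactory receptor genes, 830 of them, with the 95th percentile of their mean values at 5.03, served to describe the signal of genes not expected in bone marrow, since no detection calls were used here.

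The named genes were set by a rule: the 12 largest differences in each direction with adjusted p under 0.05 and groups that do not overlap, leaving out gene models without a name, clone names, small RNAs and olfactory receptors; all members of the retinoid lists with adjusted p under 0.05 and at least 2-fold, with a fixed set of retinoid genes named in any case; up to 4 members per direction of each other list; and Kit and Csf1r. It gave 160 genes, and 17 of that fixed set were analysed here, all but Dhrs3 and Rbp1. The text gives examples from these.

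The code was tested on simulated data with 15830 genes and the arrays' own spread, 200 of them changed. Of genes changed by a log2 of 0.5, 2.99% were recovered, 37.3% at 1 and 78.8% at 2, and 5.95% of calls were of unchanged genes. With no change, 0 genes were called. When the lysosome genes were raised by 1, camera called that list and 0 of the 31 lists that share no gene with it. The simulated noise was independent between genes, while the estimated correlation in the data reached 0.69, for cholesterol synthesis genes. The simulation therefore does not test the preset correlation. Recovery also depends on how many genes change, and 3708 were called in the data.

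Alternatives fixed before the data were examined were the mean of the probe sets or the brightest probe set per gene, quantile normalization, subtraction of each array's median, removal of genes below the olfactory receptor level, trend and robust settings or no moderation in limma, probe sets tested singly, a block for the sample number, each sample left out in turn, and the median of all genes as the signal level. The median of probe sets above the olfactory receptor level, and the signal counts without each sample, were chosen after the data were seen. After the results were seen, 5 further lists (amino acid response, endoplasmic reticulum stress, oxidant defence, mature neutrophil and immature neutrophil genes) were tested in the same way for the closing observations, with adjustment over these 5.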

Results

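Gene expression was measured by exon array in 2 kinds of cultured mouse bone marrow cells, in a study of the routes of retinoid synthesis in these cells. Retinoids are vitamin A (retinol) and its derivatives. Retinol is oxidized to retinaldehyde by retinol dehydrogenases, and retinaldehyde to retinoic acid, the ligand of the retinoic acid receptors, by aldehyde dehydrogenases. Macrophages were grown from bone marrow cells without surface Kit for 4 days with macrophage colony-stimulating factor. Kit+ progenitor cells, selected on magnetic beads for the stem cell factor receptor Kit, were expanded for 4 days with stem cell factor, Flt3 ligand, interleukin 3 and thrombopoietin. The labels give 3 samples per group, each on its own array, so 6 arrays limit the precision. The cultures also differed in medium and starting cells, so a difference between the groups is one of cell type and culture together. Median log2 signal per array lay between 6.08 and 6.16. Kit+ replicate 2 stood apart at low signals, with a lower quartile of 4.48 against 4.23 to 4.32 on the other 5 arrays. The median SD of a gene was 0.179 in macrophages and 0.229 in Kit+ cells, and in Kit+ cells 0.152 without replicate 2, against 0.212 without replicate 1 and 0.196 without replicate 3. Without Kit+ replicate 2, 3464 genes passed in limma in place of 3708. All differences below are macrophage minus Kit+ on the log2 scale, with the standard error (SE) of the fit and 3 samples per group.

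Macrophages and Kit+ cells differed in 3708 of 15830 genes at adjusted p under 0.05 in limma, 1789 higher and 1919 lower in macrophages. The receptors that define the cultures went with their labels. Kit was lower in macrophages (-3.41, SE 0.16, mean 4.48 ± 0.13 (SD, n = 3) against 7.89 ± 0.20, adjusted p = 1.93e-05), and Csf1r, the receptor for macrophage colony-stimulating factor, was higher (2.09, SE 0.19, 10.67 ± 0.17 against 8.58 ± 0.30, adjusted p = 0.000303). For comparison, 95% of 830 olfactory receptor genes, which are not expected in these cells, lay below 5.03. A difference from a group below that level is one from a signal not told from background, so its size and rank are uncertain. The largest measured difference upward was Akr1b8, an aldo-keto reductase, whose Kit+ signal was below the level (7.41, SE 0.38, 10.27 ± 0.13 against 2.86 ± 0.82, adjusted p = 2.62e-05). It was followed by Folr2 (5.92), the macrophage-secreted Cd5l (5.40), the scavenger receptor Cd36 (5.40), the glutathione transferase Gsta3 (5.25), Fabp7 (5.02), Gas6 (4.82), Ms4a7 (4.80), the scavenger receptor Stab1 (4.77), Igf1 (4.75), the protease Plau (4.73) and Ednrb (4.62). The largest measured difference downward was Mcpt8, a basophil protease, whose macrophage signal was below the level (-8.24, SE 0.13, 3.23 ± 0.08 against 11.47 ± 0.07, adjusted p = 5.39e-07). Ms4a3 (-7.81), Nkg7 (-7.41), the neutrophil granule protein Mpo (-7.06), the mast cell carboxypeptidase Cpa3 (-6.82), Ctsg (-6.81), Gzmb (-6.69), Prtn3 (-6.56), Ela2 (-6.48), Socs2 (-6.35, 1 probe set), Serpina3g (-6.25) and Plac8 (-6.23) followed. Below the level in the dimmer group were also Folr2, Cd5l, Gsta3, Fabp7 and Ednrb in Kit+ cells, and Ms4a3, Nkg7, Cpa3, Gzmb, Socs2 and Serpina3g in macrophages. Ela2 is the platform's older symbol and could not be tied to 1 current gene, and Mcpt8, Serpina3g and Akr1b8 belong to families of similar genes whose probes may cross-hybridize. A difference of 2-fold or more was met by 1775 of the called genes, 931 higher and 844 lower. Groups did not overlap in 40.4% of all genes, against 10% by chance. The count fell to 1780 genes when the probe sets were tested singly and at least 0.5 of a gene's had to pass in one direction. The median of all genes was -0.10. With each array's median subtracted it became 0.03, and 62.3% of the called genes were higher in macrophages in place of 48.2%.

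The retinol and retinaldehyde list joined enzymes of retinol oxidation, the first step of retinoic acid formation, with enzymes of retinaldehyde reduction, which runs the other way. Of 23 measured genes 4 were higher in macrophages and 1 was lower, with the same counts adjusted over the list alone. The list therefore does not tell oxidation from reduction. The higher genes were Akr1b8, Dhrs4 (0.62, SE 0.18, adjusted p = 0.0416, named after its value was seen), the carbonyl reductase Cbr1 (1.53, SE 0.20) and Dhrs9, a short-chain dehydrogenase that oxidizes retinol (1.04, SE 0.20, 7.16 ± 0.35 against 6.12 ± 0.16, adjusted p = 0.00989). Of the 12 probe sets of Dhrs4, 2 passed as higher and 1 as lower in macrophages. The call for Dhrs9 was not met by its brightest probe set (0.45, adjusted p = 0.0753). Rdh12 was lower (-1.49, SE 0.18), with a macrophage mean of 4.80, below the olfactory receptor level. Rdh10, the main retinol dehydrogenase of the embryo, lay at 6.16 ± 0.21 and 5.98 ± 0.21 (adjusted p = 0.529). As a set these genes missed the threshold (camera adjusted p = 0.0509, and adjusted p = 0.313 with an estimated correlation). They passed without macrophage replicate 2 (adjusted p = 0.0390), macrophage replicate 3 (adjusted p = 0.0473) or Kit+ replicate 3 (adjusted p = 0.0179), and with the mean of probe sets (adjusted p = 0.0186). Dhrs3 and Rbp1 were not analysed here.

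The aldehyde dehydrogenases and aldehyde oxidases split: of 23 genes, 4 were higher and 4 lower in macrophages (5 and 5 adjusted over the list alone), with camera adjusted p = 0.447. Aldh3b1 was higher (1.52, SE 0.15, 8.34 ± 0.04 against 6.82 ± 0.22, adjusted p = 0.000481), as was Aldh1l1, a folate enzyme (1.16, SE 0.18). Aldh18a1, which makes a precursor of proline (-2.01, SE 0.16), the mitochondrial folate enzyme Aldh1l2 (-2.61, SE 0.21) and Aldh3b3 (-4.40, SE 0.65, 1 probe set) were lower. The macrophage means of Aldh1l2 (3.98) and Aldh3b3 (3.81) and the Kit+ mean of Aldh1l1 (4.87) were below the olfactory receptor level. The 3 retinaldehyde dehydrogenases gave low signals. Aldh1a1 lay at 4.01 ± 0.21 in macrophages and 4.70 ± 0.35 in Kit+ cells (-0.69, SE 0.21, adjusted p = 0.0538). Aldh1a2 lay at 3.47 ± 0.50 and 3.27 ± 0.34 (adjusted p = 0.667). Aldh1a3 was lower in macrophages (4.88 ± 0.25 against 5.51 ± 0.15, -0.63, SE 0.17, adjusted p = 0.0370). Both means of Aldh1a1 and Aldh1a2, and the macrophage mean of Aldh1a3, were below the olfactory receptor level of 5.03. The call for Aldh1a3 ended with the brightest probe set (-0.34, adjusted p = 0.465), quantile normalization (-0.43, adjusted p = 0.0953), array medians subtracted (-0.50, adjusted p = 0.0777), and without macrophage replicate 1 or 3 or any 1 of the 3 Kit+ samples (-0.71 to -0.50, adjusted p = 0.0502 to 0.110), where the difference stayed near its size. It also ended with bright probe sets (-0.38, adjusted p = 0.132). Aldh1a1 passed without Kit+ replicate 1 (-0.89, adjusted p = 0.0199) and with the mean of probe sets (-0.70, adjusted p = 0.0358), and was higher in macrophages at its brightest probe set (0.38, adjusted p = 0.349).

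Of 12 genes of retinoid uptake and binding, 3 were higher in macrophages and none was lower, also when adjusted over the list alone (camera adjusted p = 0.492). They were Lrp1, a receptor that takes up lipoprotein remnants (3.20, SE 0.14, in all 92 of its probe sets), the fatty acid and retinoic acid binding protein Fabp5 (2.95, SE 0.29, 1 probe set) and Stra6l (1.43, SE 0.24, with a Kit+ mean of 4.96, below the olfactory receptor level). The median of this list was -0.22 and its mean 0.38. Crabp1 and Crabp2 lay between 4.13 and 4.89 in both groups, with adjusted p = 0.728 and adjusted p = 0.771. Among 12 genes of retinyl ester formation, hydrolysis and carotenoid cleavage, 2 were higher and 2 lower, with 4 lower adjusted over the list alone (camera adjusted p = 0.644). The higher genes were the lipases Lpl (4.18, SE 0.14) and Lipa, the lysosomal acid lipase (3.03, SE 0.13). Dgat1, which can esterify retinol, was lower (-1.35, SE 0.19). Lrat, which forms retinyl esters, lay at 4.04 ± 0.39 and 4.03 ± 0.57 (adjusted p = 0.989).

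Retinoid receptors and their partners differed in both directions, 4 higher and 4 lower of 17 genes (4 and 5 adjusted over the list alone, camera adjusted p = 0.779). Rxra was higher in macrophages (1.77, SE 0.19, 7.93 ± 0.10 against 6.16 ± 0.33, adjusted p = 0.000610), as was the coactivator Ncoa3 (1.06, SE 0.14). Rxrb (-1.40, SE 0.17), Vdr (-1.28, SE 0.15) and Rara (-1.18, SE 0.15, 7.56 ± 0.17 against 8.75 ± 0.14, adjusted p = 0.00139) were lower. Vdr lost its call at its brightest probe set (-0.06, adjusted p = 0.784), and its macrophage mean, 4.97, was below the olfactory receptor level. Rarb, Rarg and Rxrg did not pass, with differences of 0.14, -0.02 and -0.24, and Rarg passed with the mean of probe sets (-0.34, adjusted p = 0.0366). Rarb (4.29 in macrophages and 4.15 in Kit+ cells) and Rxrg (3.85 and 4.09) lay below the olfactory receptor level in both groups, and Rarg (6.18 and 6.20) above it. None of 9 genes of retinoic acid breakdown passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.779). Cyp26a1 lay at 3.29 ± 0.56 and 3.63 ± 0.02 (adjusted p = 0.418) and Cyp26b1 at 5.07 ± 0.07 and 5.50 ± 0.15 (adjusted p = 0.0634), and Cyp26a1 passed without macrophage replicate 3 (-0.66, adjusted p = 0.0380) and Cyp26b1 with genes below the olfactory receptor level removed, where fewer genes were tested (-0.43, adjusted p = 0.0225). Of 10 genes that retinoic acid induces in other cells, 3 were lower and none higher, with 4 lower adjusted over the list alone (camera adjusted p = 0.190). Only 3 of the 10 lay above the olfactory receptor level in macrophages and 4 in Kit+ cells. Cebpe, a transcription factor of late neutrophil formation, was -2.85 (SE 0.24) and the transglutaminase Tgm2 -1.04 (SE 0.20), the latter past the threshold with all probe sets and not with its brightest, where the difference was about as large (-1.004, adjusted p = 0.0841).

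**Figure D1:**
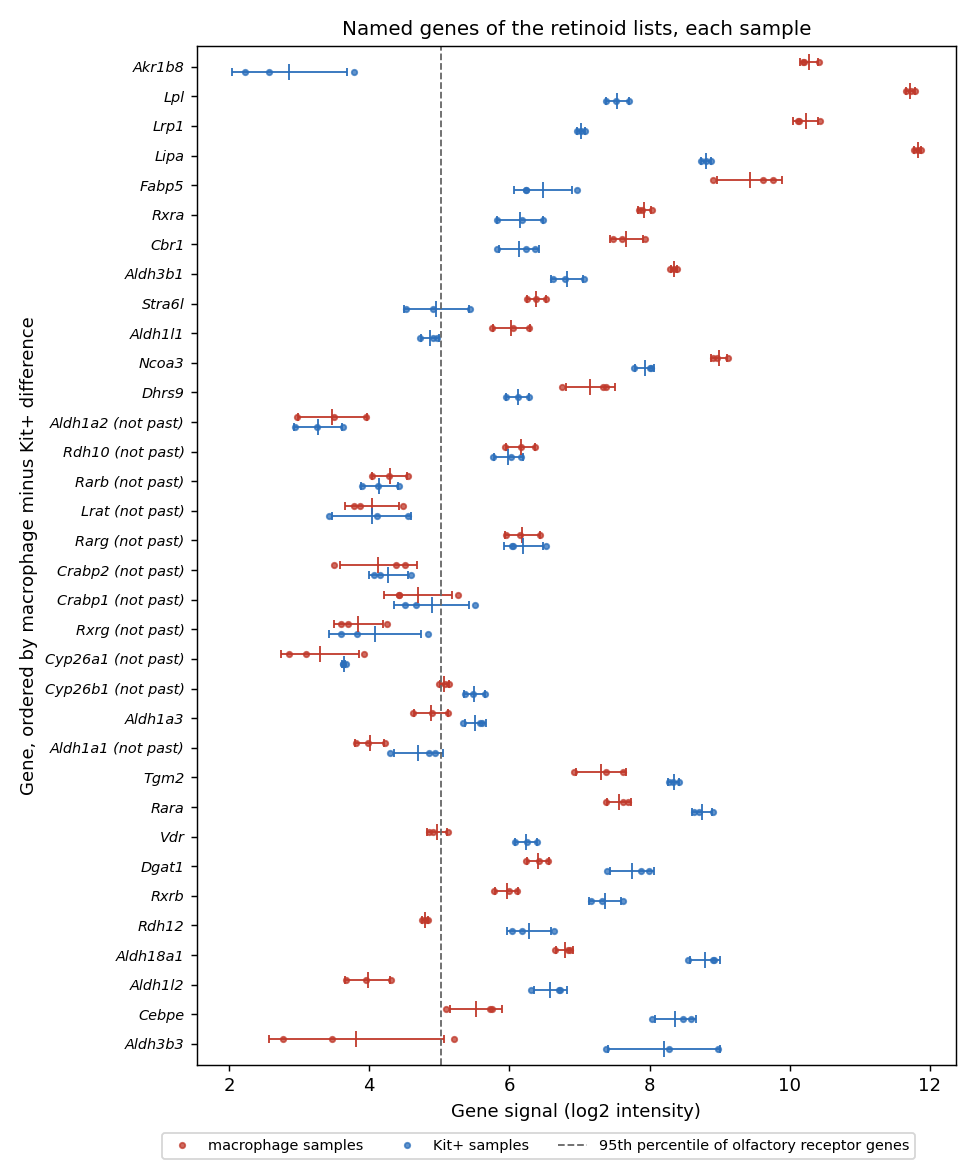
Log2 signal (x axis) of the named genes of the retinoid lists (y axis) in each macrophage (red) and Kit+ (blue) sample, with the mean (tick) and SD (bar) of 3 samples and a dashed line at 5.03, the 95th percentile of olfactory receptor genes. Akr1b8 lies at 10.27 in macrophages and 2.86 in Kit+ cells, and Aldh1a1 and Aldh1a2 have both group means left of the line.

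Macrophage genes and genes of the lysosome were higher in macrophages as sets. Of 20 macrophage markers 16 were higher and none was lower, with 1 lower adjusted over the list alone (camera adjusted p = 3.6e-13, and adjusted p = 0.0198 with an estimated correlation). Trem2 (3.86, SE 0.14), the mannose receptor Mrc1 (3.30, SE 0.19) and Marco (2.93, SE 0.19) led. Of 24 lysosome genes 23 were higher, also adjusted over the list alone (camera adjusted p = 1.64e-17, and adjusted p = 0.0198 with an estimated correlation), among them the proteases Lgmn (3.69, SE 0.23) and Ctsl (2.87, SE 0.13). Genes of lipid export, with Apoe (3.56, SE 0.17), were higher in 9 of 19 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000785, and adjusted p = 0.313 with an estimated correlation). Cholesterol synthesis genes passed as a set (camera adjusted p = 0.00414, and adjusted p = 0.589 with an estimated correlation), with 3 of 19 higher, also adjusted over the list alone, among them Msmo1 (1.30, SE 0.18).

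Complement, Toll-like receptor, interferon and immediate early gene lists were also higher in macrophages as sets, though none of them passed with an estimated correlation. Of 16 complement and Fc receptor genes 11 were higher, including C3ar1 (2.84, SE 0.14) and C1qb (2.75, SE 0.22), while complement component C3 itself was lower (-4.56, SE 0.19). The counts were the same adjusted over the list alone (camera adjusted p = 9.86e-05, and adjusted p = 0.160 with an estimated correlation). Of 33 Toll-like receptor and inflammatory cytokine genes 20 were higher and 2 lower (22 and 3 adjusted over the list alone, camera adjusted p = 4.12e-08, and adjusted p = 0.160 with an estimated correlation). The chemokines Ccl7 (3.90, SE 0.17) and Ccl12 (3.89, SE 0.39) and the RNA-sensing receptors Tlr8 (3.63, SE 0.47) and Tlr7 (3.15, SE 0.19) were higher, and Il6 was lower (-5.09, SE 0.19). Of 20 interferon-stimulated genes 9 were higher and 1 was lower (12 and 1 adjusted over the list alone, camera adjusted p = 2.86e-05, and adjusted p = 0.325 with an estimated correlation), with Ifi204 at 2.32. Ifit1 passed (1 probe set) with both group means, 5.00 and 2.67, below the olfactory receptor level. Of 20 immediate early and heat shock genes 8 were higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.160 with an estimated correlation). That set did not pass with genes below the olfactory receptor level removed (camera adjusted p = 0.123). Atf3 (3.02, SE 0.15), Dusp1 (2.47, SE 0.15) and Fos (2.01, SE 0.22) were higher, and Trib3 (-3.49, SE 0.17) and Ddit3 (-2.01, SE 0.14), both stress-induced, were lower.

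Genes of stem and progenitor cells and of several granulocyte lineages were lower in macrophages. Of 23 progenitor genes 19 were lower and none was higher (20 adjusted over the list alone, camera adjusted p = 7.19e-11, and adjusted p = 0.0712 with an estimated correlation), among them the transcription factor Myb (-4.99, SE 0.15), Kit (-3.41), Cd34 (-2.99, SE 0.58) and Gata2 (-2.65, SE 0.18). Primary granule and promyelocyte genes, called primary granule genes below, were lower in 8 of 10, also adjusted over the list alone (camera adjusted p = 2.4e-10, and adjusted p = 0.0250 with an estimated correlation). All 13 later neutrophil granule genes were lower on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 1.58e-10, and adjusted p = 0.160 with an estimated correlation), among them Chil3 (-5.96, SE 0.38), Ltf (-4.78, SE 0.37) and Camp (-4.61, SE 0.32). Mast cell and basophil genes were lower in 12 of 16 and higher in 1, the same adjusted over the list alone (camera adjusted p = 7.15e-09, and adjusted p = 0.0250 with an estimated correlation). The IgE receptor chain Fcer1a was -5.33 (SE 0.34), and the transcription factor Mitf was the higher one (1.47, SE 0.14). Of 6 eosinophil genes 4 were lower and 1 was higher on both adjustments, including adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.325 with an estimated correlation), with Prg2 at -5.45 (SE 0.43), and without Kit+ replicate 2 the set did not pass (adjusted p = 0.0598).

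Platelet, monocyte, dendritic cell and ribosome biogenesis genes completed the sets that were lower in macrophages. Of 11 megakaryocyte genes 9 were lower, such as Gp9 (-3.52, SE 0.34) and Ppbp (-3.26, SE 0.23), and Pf4 was higher (0.80, SE 0.16), the same adjusted over the list alone (camera adjusted p = 1.57e-05, and adjusted p = 0.150 with an estimated correlation). Of 10 monocyte genes 6 were lower, with Vcan at -3.36 (SE 0.35) and Spn at -2.75 (SE 0.20), and 2 were higher, with the chemokine receptor Cx3cr1 at 1.39 (SE 0.19). Adjusted over the list alone 7 were lower and 2 higher (camera adjusted p = 0.00800, and adjusted p = 0.313 with an estimated correlation). Of 20 dendritic cell and MHC class II genes 10 were lower and 3 higher (12 and 4 adjusted over the list alone, camera adjusted p = 0.0167, and adjusted p = 0.429 with an estimated correlation). The MHC class II genes Cd74 (-1.64, SE 0.21) and H2-DMa (-1.70, SE 0.16) were lower, and Cd83 (1.56, SE 0.29) and Itgax (1.28, SE 0.21) higher. Of 18 ribosome biogenesis and MYC target genes 8 were lower and none was higher (13 adjusted over the list alone, camera adjusted p = 4.77e-05, and adjusted p = 0.345 with an estimated correlation), with Myc itself at -1.25 (SE 0.13).

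**Figure D2:**
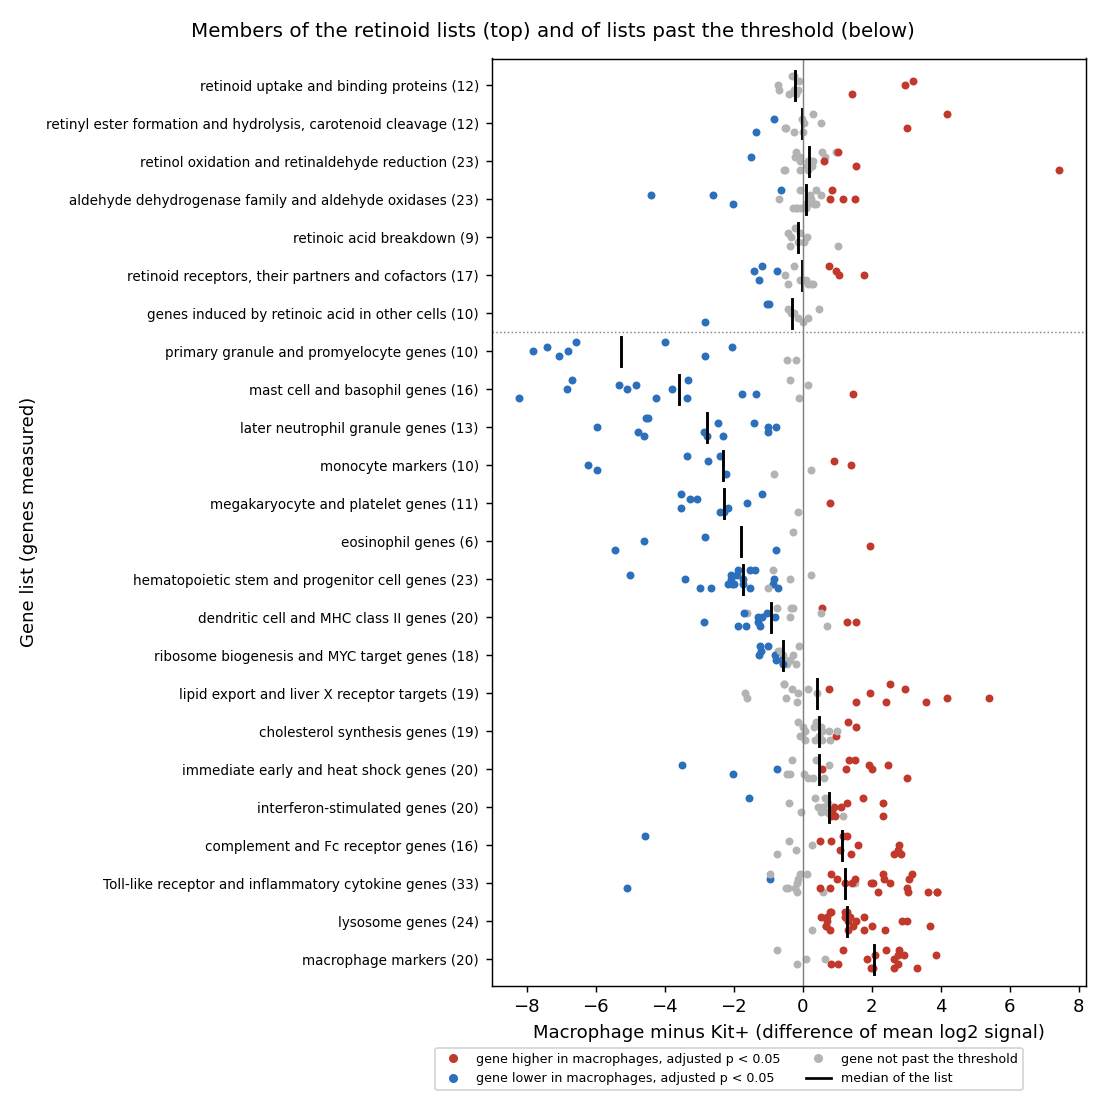
Difference of mean log2 signal, macrophage minus Kit+ (x axis), of each measured gene in the 7 retinoid lists (above the dotted line) and the 17 lists past the threshold (below it), with the number of genes measured in parentheses. Red points are higher and blue points lower in macrophages at adjusted p under 0.05, grey points did not pass, and the black tick is the list's median, which was 2.06 for macrophage markers and -5.28 for primary granule genes.

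The other 11 lists did not pass. Only 1 of 20 mitosis genes differed in limma, none adjusted over the list alone (camera adjusted p = 0.492): Kif11 was -0.44 (SE 0.13, adjusted p = 0.0432), and it passed in none of the fits without 1 array, with differences of -0.47 to -0.40 (adjusted p = 0.0552 to 0.132), nor with array medians subtracted (-0.31, adjusted p = 0.167). Of 20 DNA replication genes 5 were lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0900), with Cdc45 at -1.07 (SE 0.14). As a set they passed without macrophage replicate 3 (adjusted p = 0.0467) and without Kit+ replicate 2 (adjusted p = 0.0151). Markers of other cells were mixed. Erythroid genes (1 higher and 2 lower of 11, 1 and 3 adjusted over the list alone) gave camera adjusted p = 0.312, with Car2 at -3.42 and Tfrc at 2.43. B cell genes (3 higher of 12 on both adjustments) gave 0.149 and T and NK cell genes (1 higher and 4 lower of 14 on both) 0.447. Blnk (3.63), Il7r (3.31) and Cd28 (2.75) were higher, and Klrd1 (-3.32) and Thy1 (-3.30) lower. Osteoclast genes (3 higher and 2 lower of 12, 5 and 2 adjusted over the list alone) gave 0.447, with Atp6v0d2 at 2.38 and Itgb3 at -2.18. Stromal genes (1 higher and 2 lower of 16 on both adjustments) gave 0.190, and endothelial genes (2 higher and 1 lower of 10 on both) 0.779, with Igfbp7 at -2.79 (-0.16 at its brightest probe set, adjusted p = 0.403) and Pecam1 at -3.91. Growth factor receptors (2 higher and 5 lower of 13 on both) gave 0.154, with Csf2rb at -2.16. Glycolysis genes (2 and 2 of 14 on both) gave 0.743, with the glucose transporters Slc2a1 at 1.02 and Slc2a3 at -2.09. Reference genes (1 and 1 of 8 on both) gave 0.654, with Gusb at 1.56 and Rplp0 at -1.32. Median and mean differed in sign for retinyl ester genes (-0.01 and 0.39), aldehyde dehydrogenases (0.11 and -0.19), B cell genes (-0.06 and 0.63), endothelial genes (0.01 and -0.28), glycolysis genes (0.03 and -0.06) and reference genes (-0.005 and 0.03). The test pointed higher for all 6, for retinoid uptake and binding against a median of -0.22, and for retinoid receptors against a median of -0.02 and a mean of -0.03.

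Signal above the 95th percentile of olfactory receptor genes was reached by 9423 genes in macrophages and 9934 in Kit+ cells, with 329 above it in macrophages alone, 840 in Kit+ cells alone and 9094 in both. With the brightest probe set of each gene the counts in 1 group alone were 211 and 553. With 1 sample left out they were 308 to 400 in macrophages alone and 705 to 1000 in Kit+ cells alone. The closest pair, 400 and 705, came without Kit+ replicate 2, the array that stood apart at low signals. Of the retinoid lists, 12 of 23 retinol and retinaldehyde genes were above it in macrophages and 11 in Kit+ cells, 11 and 13 of 23 aldehyde dehydrogenase and oxidase genes, 13 and 14 of 17 receptor genes, and 1 of 9 breakdown genes in each. For retinoic acid targets it was 3 and 4 of 10, for uptake and binding 4 and 5 of 12, and for retinyl esters 5 and 6 of 12. These counts describe the signal and carry no test.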

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

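The median over bright probe sets and the signal counts without each sample were chosen after the data were seen; the other settings were fixed before. The count of genes stayed within 1.5 times the reported 3708 (2937 to 4843), and was 2600 to 3464 with 1 sample left out, except with probe sets tested singly (1780 genes, 972 higher and 809 lower, 1 of them counted in both), where the rule counts fewer genes by construction. No called gene changed sign with quantile normalization, median subtraction, the dim-gene filter or a sample left out. The filter leaves each difference as it was and median subtraction moves all of them by the same small amount, so these 2 settings do not test the sign. Leaving out a sample cannot turn the sign of a gene whose groups do not overlap, which held for every called gene named here. With the brightest probe set 237 called genes changed sign, 15 of them called the other way. With the mean of probe sets 2 did, and with bright probe sets 55, 3 of them called the other way. Subtracting array medians raised the share of higher calls from 48.2% to 62.3% and kept 3110 calls. Above the olfactory receptor level in 1 group alone were 211 genes in macrophages and 553 in Kit+ cells with the brightest probe set, in place of 329 and 840.

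Of the 17 lists past the threshold 4 passed with an estimated correlation, and 25 lists passed with fry. The retinol and retinaldehyde list (adjusted p = 0.0509) passed with the mean of probe sets (0.0186), quantile normalization (0.0287), the dim-gene filter (0.0446), bright probe sets (0.0416) and fry (0.0137), and ranged over 0.0179 to 0.122 with 1 sample left out, passing without macrophage replicate 2 or 3 or Kit+ replicate 3. Of the lists past the threshold, eosinophil genes did not pass with the brightest probe set (0.113), bright probe sets (0.0748) or without Kit+ replicate 2 (0.0598), nor immediate early and heat shock genes with the dim-gene filter (0.123), nor cholesterol synthesis genes with fry (0.193). DNA replication genes passed with the brightest (0.0436) and quantile normalization (0.00848), and mitosis genes with the latter (0.0344). With fry, DNA replication (0.0404), B cell (0.00115), T and NK cell (0.0150), stromal (0.0226) and growth factor receptor genes (0.000697) passed. Retinoic acid targets passed with the mean (0.0378) and fry (0.0108), and with fry also uptake and binding (0.0136) and retinyl esters (0.00170). Some lists turned direction, and passed neither as reported nor where they turned: retinoid receptors with the mean (adjusted p = 0.933), the dim-gene filter (0.924), bright probe sets (0.753) and fry (0.475); retinyl esters with bright probe sets (0.930); retinoic acid breakdown with the brightest (0.805), quantile normalization (0.861) and, of the fits with 1 sample left out (0.583 to 0.985), only without macrophage replicate 1 (0.985); endothelial genes with the mean (0.957), the brightest (0.394), fry (0.283) and, of the fits with 1 sample left out (0.479 to 0.969), only without Kit+ replicate 1 (0.969); glycolysis with the brightest (0.953) and quantile normalization (0.943); and reference genes with quantile normalization (0.781). The cause was not tested.

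Of the 160 named genes, 127 kept direction and side of the threshold with the brightest probe set, and 154 with the mean, 153 with quantile normalization, 155 with medians subtracted, 140 of 141 with the dim-gene filter, which removed the rest, 145 of 155 with bright probe sets and all 160 with trend and robust settings. Log2 differences that turned sign were, with the brightest probe set, Aldh1a1 0.38, Aldh1a2 -0.28, Lrat -0.11, Crabp2 0.50, Cyp26a1 0.041, Rarb -0.53, Cd22 -0.44, Cd209a -0.13, Tnfrsf11a -0.17, Eng -0.27, Il1a 0.63, Oas2 -0.064, of which Cd22 passed both ways; with the mean, Aldh1a2 -0.10, Lrat -0.011, Rarb -0.20; with quantile normalization, Crabp1 0.012, Crabp2 0.051, Rarg 0.037; with medians subtracted, Rarg 0.12; and with bright probe sets, Lrat -0.11, Cyp26b1 0.029, Rarb -0.19, Eomes 0.20. With 1 sample left out, sign was not fixed for Aldh1a2 (-0.039 to 0.46), Crabp2 (-0.33 to 0.17), Lrat (-0.29 to 0.27), Rarg (-0.15 to 0.14), Rxrg (-0.49 to 0.13), Crabp1 (-0.47 to 0.11). The cause was not tested. Of these, Cd22, Cd209a, Tnfrsf11a, Eng, Il1a, Oas2 and Eomes had passed in the reported fit. Genes near the olfactory receptor level, among them the retinaldehyde dehydrogenases, carry the least signal over background. Over all alternatives adjusted p ranged as follows: Dhrs9 0.00142 to 0.0753, Vdr 0.000110 to 0.784, Tgm2 0.000569 to 0.0841, Igfbp7 1.12e-06 to 0.403, Aldh1a1 0.0199 to 0.363, Aldh1a3 0.00290 to 0.465, Rarg 0.0366 to 0.998, Cyp26a1 0.0380 to 0.909, Cyp26b1 0.0225 to 0.929, Kif11 0.00756 to 0.167, Cd22 0.00187 to 0.0434.

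The sample numbers gave no sign of pairs: deviations from the group means correlated across genes by -0.026, -0.039 and -0.011 for samples 1, 2 and 3. With 3 samples per group a small shared effect could be missed, so samples from the same mice are not excluded. With the number as a replicate block 2937 genes and 18 lists passed, the added list being retinol and retinaldehyde genes (adjusted p = 0.0436). Aldh1a3 (-0.63, adjusted p = 0.0677) and Kif11 (-0.44, adjusted p = 0.108) lost their calls under the block, which does not change their differences.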

Other observations

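The 5 gene lists below were chosen after the results above were seen, and the genes named from them after their values were. Both neutrophil tests were chosen after results they rest on were seen: those of the late and primary granule lists, and of 6 of the 9 immature neutrophil genes. Genes that cells raise when amino acids run short were lower in macrophages: 23 of 26 passed in limma and none was higher (camera adjusted p = 1.63e-16 over the 5 lists, and adjusted p = 0.0428 with an estimated correlation). Among them were asparagine synthetase Asns (-2.76), the serine enzymes Psph (-2.07) and Shmt2 (-2.47), the amino acid transporter Slc7a5 (-3.56) and Cth, which makes cysteine (-4.10, with a macrophage mean of 4.55, under the olfactory receptor level).

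Genes of oxidant defence were higher in macrophages: 14 of 27 were higher and 1 lower (camera adjusted p = 2.61e-08, and adjusted p = 0.0428 with an estimated correlation). Heme oxygenase Hmox1 was 3.67, peroxiredoxin Prdx1 3.29, Srxn1 2.49 and catalase Cat 2.04, and the cystine transporter Slc7a11, which also stands in the amino acid list, was the lower one (-1.26). The list's median was 0.824, against -0.10 for all genes. Akr1b8 and Gsta3, which prompted the test, are not in the list.

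Aldh18a1, Aldh1l2, Trib3 and Ddit3 were lower in macrophages. A difference in array medians does not account for this, since the smallest of the 4 differences was -1.88 after array medians were subtracted. That subtraction moved the median of all genes only from -0.10 to 0.03, so no other outcome was likely. Scaling that depends on the signal level was not tested by it. Trib3 and Ddit3 respond to endoplasmic reticulum stress as well as to amino acid shortage and stand in neither list. Genes of endoplasmic reticulum stress had a median of 0.0353 (1 higher and 2 lower of 21, camera adjusted p = 0.277), which goes against a fall of the listed genes as a set. Herpud1 (-1.37) and Xbp1 (-1.18) were the lower ones and Dnajb9 (0.65) the higher one. Stress that acts through genes of the amino acid list would not be seen by this list, so the 2 lists do not separate the causes. The amino acid list had a median of -1.38, so a lower amino acid response in macrophages may be the source. The 2 cultures used different media, so medium and cell type stay open and untested.

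Late neutrophil genes were spread widely, from S100a8 at 11.76 on the macrophage arrays against 12.75 on the Kit+ arrays, S100a9 at 11.82 against 12.83 and Mmp8 at 9.85 against 10.62 to Camp at 7.69 against 12.29, Ltf at 5.57 against 10.35 and Chil3 at 5.24 against 11.20. The list of primary granule and promyelocyte genes was spread too, with Igsf6 at 9.54 against 9.75 and Mpo at 5.66 against 12.72, and not all its members are granule genes. Cells of the Kit+ culture's kind would bring both sets in 1 proportion, and the median differences were -2.77 and -5.28, 2.51 apart (two-sided permutation p = 0.0485 over 13 and 10 genes, which are not independent). This is the contrast that prompted the comparison and no separate test of it. Cells carried over in the Kit+ culture's own mix would bring Mpo, Ctsg and Prtn3 too. These were 134-fold, 113-fold and 94.5-fold lower in macrophages, though still above the olfactory receptor level. The late list's median was 14.7% of the Kit+ signal, so these values argue against that mix as the main source for the late list. They do not cover a carried part of that culture rich in late neutrophils. Genes of mature neutrophils lay 3.46 above genes of immature ones (medians -1.03 over 19 genes, 10 lower and 1 higher, and -4.49 over 9, all lower, two-sided permutation p = 0.00198), but by 1.06 above the 3 immature genes not seen earlier (median -2.09, two-sided permutation p = 0.263), so the gap rests mostly on genes already seen. Mature neutrophils among the Kit-negative starting cells may add to the macrophage arrays. Whether any lasted through the 4 days of culture was not measured. The comparison leaves this undecided, with camera adjusted p = 4.22e-05 for the mature and 9e-09 for the immature list (adjusted p = 0.211 and 0.106 with an estimated correlation). Expression by the macrophages themselves stays open and would give the same difference: 17 of the 19 mature genes lay above the olfactory receptor level there, some of them known macrophage genes such as Alox5ap (11.93), and the neutrophil receptor Il1r2 lay below it (4.82).

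Aldh1a1 and Aldh1a3 had lower means on the macrophage arrays at signals near the olfactory receptor level. Of genes within 0.5 of its mean signal, 10.2% had a difference as low as that of Aldh1a1, and 14.3% as low as that of Aldh1a3, so both lie inside the central range that had been set beforehand as pointing to a shift of all dim genes. In a comparison added after that result, genes of like signal moved by a median of only -0.18 for either gene, and olfactory receptor genes by -0.088, so a common shift accounts for part of the differences at most. Whether the remainder is a difference in expression or the spread of dim genes cannot be told apart here.

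With 3 arrays against 3 there are 10 splits, so no share of splits under 0.05 can be reached. Only 1 split, the real one, gave as many genes (3708 in limma, highest other 0). At unadjusted p under 0.05 in limma it gave 5514 genes, and any other split at most 424. Only 1, again the real one, gave as many lists (17, highest other 10). Every other split places arrays of both cell types in each group. The difference between the cell types then adds to the spread within groups, so few gene calls there were likely whatever its cause. These counts therefore do not decide whether the real contrast is more than chance.

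Of 14679 probe sets with several gene symbols or none here, 1082 passed when tested singly in limma, 582 higher and 500 lower in macrophages. This is 7.37%, against 13.5% of probe sets with 1 gene symbol.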
